A study of Oryza sativa with 36 samples.

How the data were processed

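RNA of rice cultivar 9311 was measured in 35 RNA-seq runs of 8 tissues and in 1 small RNA library of their pooled RNA. Per the labels' protocols, total RNA was treated with DNase. For the mixed preparation, mRNA selected with oligo-dT beads was combined with a gel fraction of total RNA between 200 bp and 1 kb, and for the polyA preparation mRNA alone was used; cDNA was primed with random primers in both. The mixed preparation does not remove abundant short RNA species, so a few features can take most counts of such a library. For the small RNA library, RNA of 18 to 30 nt was cut from a gel, ligated to adapters at both ends and amplified by PCR, per the labels. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

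The deposited RNA-seq files hold a whole-number count per feature and no normalized values. The aligner, the genome build, the handling of reads that match several features and the use of strand are not given in the sources used here. Features that share reads with similar copies or with an antisense or overlapping neighbour are therefore uncertain. The deposited small RNA file holds the length, the count and the sequence of each distinct tag. The deposited single-end files list 4830 to 6132 features each with a count of 0, and the paired-end files list none at 0. A feature absent from a file was given a count of 0.

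The 35138 feature identifiers comprise 17679 that begin with AK, 13305 gene models named by chromosome of 9311, 794 named by scaffold and 3360 clone identifiers. None matched the table of 39387 rice genes used for names, which follows another assembly, so no symbol or function is given, and the 9 gene lists and 24 keyword lists fixed before the data were examined could not be tested. In place of named genes, 2 identifiers per direction are given: for booting panicle against callus those with the largest fitted log2 change among features with an adjusted p below 0.05, a mean of at least 10 CPM in the higher tissue and all libraries of one tissue above all of the other; for single libraries those with the largest ratio and at least 50 CPM in the higher library.

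Runs were summed to libraries by the insert size in the labels, which gave 14 libraries of 1036291 to 64373256 counts. Runs of a library differed by more than sampling noise: chi-square per degree of freedom was 1.74 to 2.75 in the 180 and 178 bp libraries, and up to 69.4 in the 360 bp library, where AK105158 varied between runs. Summing them keeps n at 4 libraries per tissue. Booting panicle and callus were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 left 22984 features, scaling was by TMM with library sizes kept as totals, and glmQLFit and glmQLFTest were used with terms for preparation and tissue and 5 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all features tested. A 0 in a whole tissue was replaced by a floor of 3 counts over the 4 libraries to give lower bounds of folds. Counts were simulated for the same 22984 features, with known changes in booting panicle against callus planted only in features with a mean of at least 5 CPM. The fit recovered 95 of 100 features changed 16-fold, 21 of 50 changed 4-fold and 0 of 50 changed 2-fold, with 6 unchanged features called, so small changes are mostly missed. Recovery at lower CPM was not tried, and no simulated library departed from its tissue as the 203 bp callus library did. The 16-fold size was added after a first simulation with 2-fold and 4-fold changes recovered few features.

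The other 6 tissues had 1 library each and no test was made. The 8 single-end libraries were scaled by TMM, a choice made after the share of the abundant features was seen, and compared as CPM plus a pseudocount of 1. A feature was counted in a pair when it reached 10 CPM and was at least 4-fold apart, and as enriched when at least 4-fold above the next highest tissue. In simulated pairs, all 200 features changed 16-fold were recovered in each of the 5 comparisons, and counting noise alone gave 0.2 to 8.5 features of 27825. A 0 in a library was replaced by a floor of 3 counts in that library. For correlations and detection the libraries were thinned to 118083 counts without the 6 abundant features and AK105158, whose share varied between runs.

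For small RNAs, lengths and first bases were counted with exact Clopper-Pearson intervals at 95%, and tags identical to the 29 listed miRNA sequences were counted. In simulated tags, all 1000 planted tags with a partner at a 3' overhang of 2 nt were found among 6000. Alternatives tried before and after the data were examined are given in the closing section. They cover the preparation term, runs as samples, a replicate block, subsets of libraries, low count filters, scaling, DESeq2 1.42.0, leaving out each library, other folds, minimums and pseudocounts, and other ways to count small RNAs. Further computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.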

Results

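The transcriptome of rice was surveyed in 8 tissues of the indica cultivar 9311 by RNA-seq: callus (undifferentiated tissue in culture), shoot and root of seedlings aged 14 days, leaf at tillering and at flowering, and panicle at booting, flowering and filling. Small RNAs were sequenced from 1 pool of total RNA of the same 8 tissues. Every tissue had 1 single-end library of 35 bp reads, for which polyA RNA was mixed with a gel fraction of total RNA. Callus and booting panicle each had 3 further paired-end libraries, named below by their insert sizes: 203, 206 and 180 bp in callus and 360, 414 and 178 bp in booting panicle. The 203 bp callus library was also of the mixed kind and the other 5 were made from polyA RNA alone. The 35 sequencing runs of these 14 libraries held 1036291 to 9176603 counts each, and 12760 to 27590 of the 35138 features were detected per run. The library titled seedling shoot carried a tissue field reading root, and the library titled seedling root carried one reading shoot, so both are named here by their titles.

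Between 79.3% and 93.4% of the counts of the 8 single-end libraries fell on 6 features, singled out after their values were seen because each took at least 3% of the counts of at least 1 such library. AK059783 alone took 61.3% in filling panicle and 32.4% in flowering leaf. Of the 6, AK059621 differed most between tissues as a ratio of shares. It took 25.4% of the counts in tillering leaf, 15.5% in flowering leaf, 11.5% in the library titled seedling shoot and 7.73% in flowering panicle. Its share was 0.547% in filling panicle, 0.284% in booting panicle, 0.133% in callus and 0.0363% in the library titled seedling root. The files do not pair these identifiers with gene names. The 6 features took 86.1% and 89.1% in the mixed callus libraries and 4.65% and 11.7% in the polyA callus libraries. In booting panicle they took 82.1% in the mixed library and 1.25%, 32.6% and 9.29% in the 360, 414 and 178 bp polyA libraries. Outside these features the single-end libraries held 118436 to 335930 counts.

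**Figure D1:**
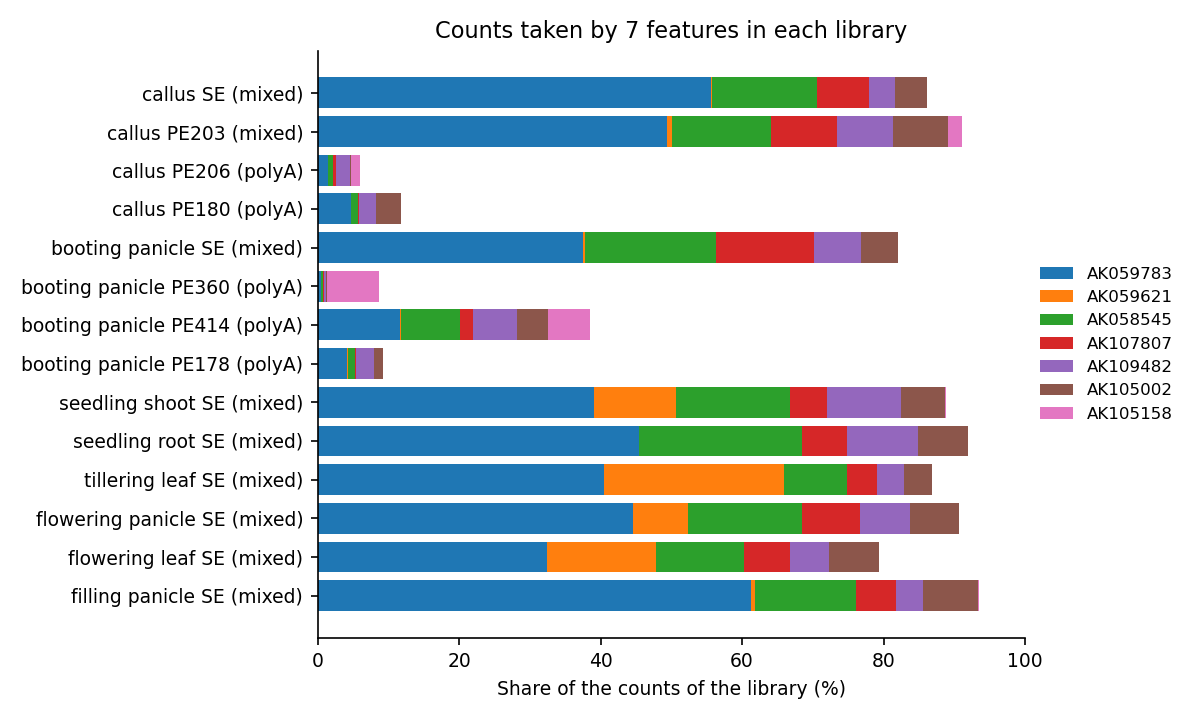
Share of the counts of each library (x axis, %) taken by the 6 abundant features and by AK105158, stacked, in the 14 libraries, with the RNA preparation in brackets (SE, single-end; PE, paired-end with insert size in bp). The mixed libraries lie between 79.3% and 93.4% for the 6 features, and AK059621 reaches 25.4% in tillering leaf.

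Callus libraries resembled each other in 3 of 4 cases. With all libraries thinned to 118083 counts outside the abundant features, Spearman's rho across features was 0.703 between the single-end and the 206 bp callus libraries, 0.725 between the single-end and the 180 bp libraries and 0.726 between the 206 and 180 bp libraries. The 203 bp callus library reached only 0.520, 0.507 and 0.480 with these, and 0.720 with filling panicle. The 4 booting panicle libraries correlated at 0.640 to 0.795. Tillering and flowering leaf correlated at 0.699, and each correlated with the library titled seedling shoot (0.527 and 0.546) above the library titled seedling root (0.319 and 0.326). Features are not independent replicates, so these values describe the libraries and carry no test. Without thinning, the median rho over 66 pairs of runs of a single library was 0.991, against 0.860 over 130 pairs of runs from different libraries of a tissue and 0.639 over 210 pairs of callus and booting panicle runs. Of the 66 pairs, 28 came from the 180 bp and 28 from the 178 bp library, and the 3 pairs of runs of the 203 bp callus library had a median of 0.858.

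**Figure D2:**
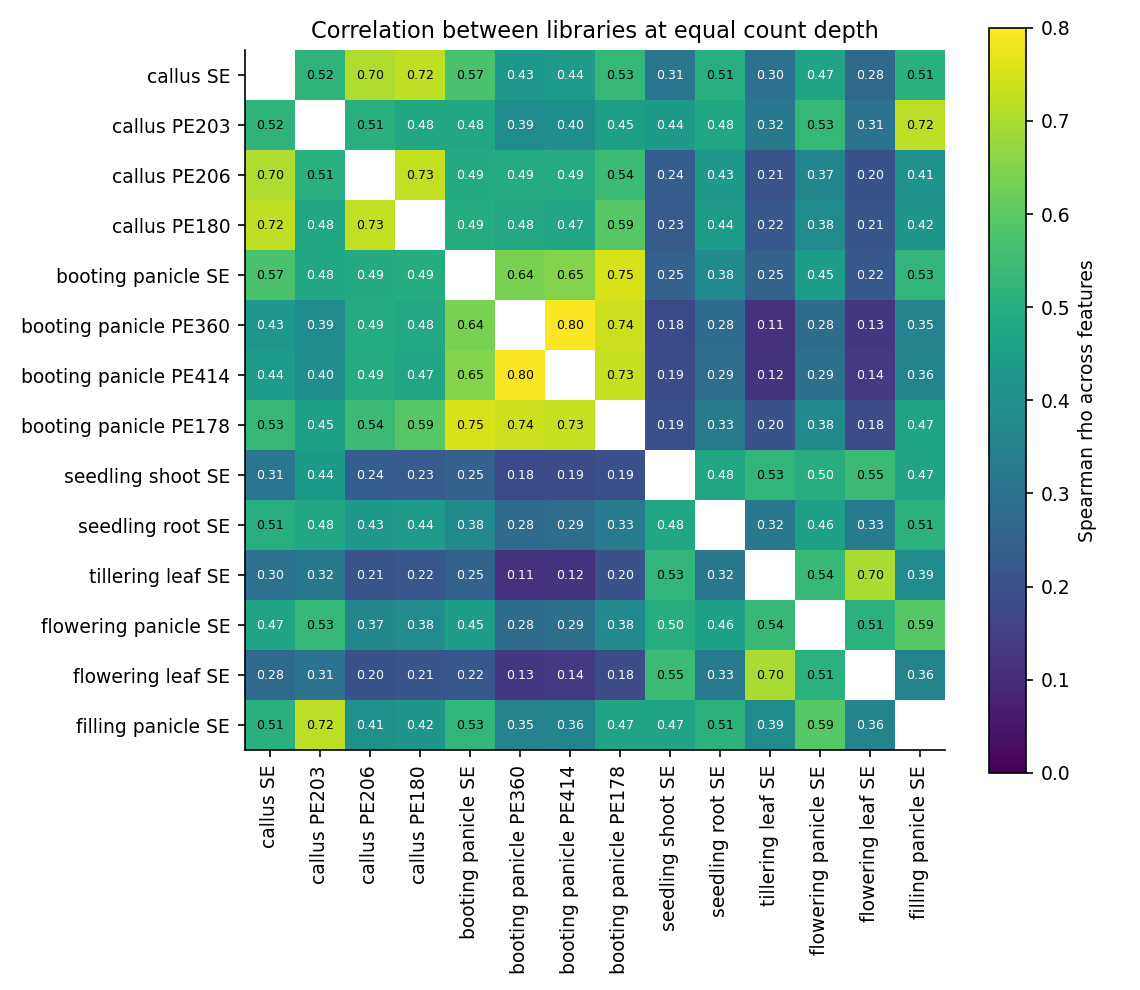
Spearman's rho across features between the 14 libraries, each thinned to 118083 counts outside the abundant features (colour and printed value; rows and columns are libraries). The 203 bp callus library has its highest value, 0.720, with filling panicle, and the leaf libraries stand apart from the booting panicle libraries.

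Features enriched in filling panicle among the single-end libraries were present in the 203 bp callus library at the level of filling panicle itself. The summed CPM of these 51 features was 101% of that in filling panicle, against 1.46% in the single-end, 2.42% in the 206 bp and 1.94% in the 180 bp callus libraries. The 75 features enriched in callus reached 18.2% of their single-end callus level in the 203 bp library, 139% in the 206 bp library and 166% in the 180 bp library, and 2.39% in filling panicle.

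**Figure D3:**
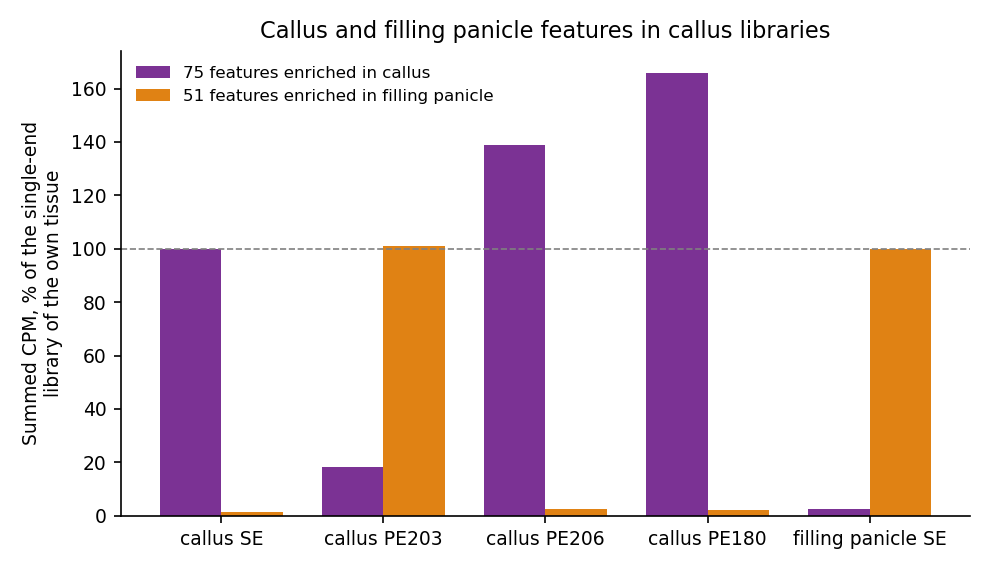
Summed CPM of the 75 features enriched in callus and of the 51 enriched in filling panicle, as a percentage of the single-end library of their own tissue (y axis), in the 4 callus libraries and filling panicle (x axis; 1 bar per library and set, without error). In the 203 bp callus library the filling panicle set stands at 101% and the callus set at 18.2%.

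Booting panicle and callus, the tissues with more than 1 library, were compared to ask which transcripts distinguish a developing inflorescence from cultured tissue. In the main fit, transcripts lower in booting panicle were more numerous and changed by more: 2675 features were lower and 1472 higher. The median log2 ratio of the tissue means was -4.10 among the former and 2.60 among the latter, with a tissue at 0 set to 3 counts over its libraries. The callus means include the 203 bp library, which held features enriched in filling panicle. The ratios were not recomputed without it, so the contrast in size may rest partly on that library. Without the preparation term 1553 were lower and 1286 higher. With runs as samples, which repeat libraries, 6988 were lower and 7275 higher. AK103558 was present in all 4 callus libraries (207 ± 225 CPM, SD, n = 4) and had 0 counts in the 4 booting panicle libraries, at least 12171-fold lower, a bound that rests largely on 532 CPM in the 180 bp library (14.5 to 159 CPM in the other 3). AK107862 likewise fell from 68.5 ± 38.1 CPM in callus to 0 counts in booting panicle, at least 4022-fold. AK058425 had 0 counts in the 4 callus libraries and 13.5 ± 4.99 CPM in booting panicle, at least 669-fold higher. It also had 0 counts in the single-end libraries of the other 6 tissues. Those libraries are shallow, and even the single-end booting panicle library held it at only 6.40 CPM, so these zeros say little about the other tissues. AK069616 rose from 0.950 ± 1.89 to 187 ± 155 CPM, a 197-fold ratio of means, and 3.78 CPM in the 203 bp callus library made up most of its callus mean.

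The main fit was edgeR's quasi-likelihood test on counts summed over the runs of each library, with 4 libraries per tissue and the RNA preparation as a covariate. Of 22984 features tested, 4147 passed an adjusted p of 0.05. The adjusted p by edgeR was 0.000376 for AK103558, 8.41e-05 for AK107862, 0.000138 for AK058425 and 0.00578 for AK069616, and all libraries of a tissue lay above all of the other for each. Among all features tested, 4338 (18.9%) had groups that did not overlap, where chance gives 2.86%. Tissue means, with the 203 bp library in callus, differed at least 10-fold for 462 of the higher and 1680 of the lower features. Features of the 3 identifier classes passed at similar rates: 17.8% of the 14864 tested identifiers that begin with AK, 18.0% of the 2785 clone identifiers and 18.8% of the 5335 gene models of 9311. The labels do not say that the libraries came from separate cultures or plants, so the p-values measure only the spread between these libraries, which may be technical. The count was 5313 without the 203 bp callus library, 2334 without the 206 bp and 2058 without the 180 bp callus library, and the features higher and lower in booting panicle were then 2292 and 3021, 675 and 1659, and 592 and 1466. AK069616 lost its call without the 206 bp library (adjusted p = 0.062 by edgeR).

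Within each tissue the libraries also allowed the mixed preparation to be set against polyA RNA alone, 3 libraries against 5. In the same edgeR fit, 82 features were higher and 9 lower in the mixed libraries at an adjusted p of 0.05. For 71 of the 82, all 3 mixed libraries lay above all 5 polyA libraries, and for 43 of the 82 both single-end libraries lay above all 6 paired-end libraries. The 6 abundant features had log2 differences of 3.94 to 7.15 in favour of the mixed preparation, and none passed, with an adjusted p by edgeR of 0.0534 to 0.278. The count rested on single libraries: it was 0 without the single-end booting panicle library (3022 features with unadjusted p below 0.05), 4 without the 178 bp booting panicle library, 4 without the 180 bp and 30 without the 206 bp callus library. DESeq2, chosen as an alternative after the data were seen, called 785. As 2 of the 3 mixed libraries were single-end, whose files list features at 0 where the paired-end files list none, and the 414 bp polyA library had 32.6% of its counts on the 6 abundant features, these counts cannot be laid to the preparation alone.

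No feature was found whose difference between booting panicle and callus depended on the preparation. For the mixed preparation the log2 ratio was taken between the single-end libraries alone, without the 203 bp callus library. For polyA it was taken between the means of the polyA libraries. Over all 22984 features, most of which were not called, these 2 ratios had the same sign for 58.8%, with a rho of 0.454. For the 4147 called features these were 88.9% and 0.792, but they had been picked for a difference over the same libraries. An edgeR fit with a term for the interaction of tissue and preparation called 0 of 25153 features, with 1220 at an unadjusted p below 0.05, and 0 of 24188 without the 203 bp callus library, with 633. With 8 libraries and few per preparation, this does not show that the preparations gave equal differences.

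Across the 8 single-end libraries, 439 features were enriched in a single tissue, with at least 10 CPM there and at least 4 times the next highest tissue. The library titled seedling root held 111 of them, callus 75, the library titled seedling shoot 74, filling panicle 51, flowering panicle 48, booting panicle 35, flowering leaf 33 and tillering leaf 12. This order depends on which tissues were sampled, as similar tissues limit each other's counts: tillering and flowering leaf correlated at 0.699. With a fold of 2, flowering leaf held the most, 237. The order also depended on the scaling: with CPM taken over the library total, booting panicle held 210, callus 120, flowering leaf 113, the library titled seedling root 94 and tillering leaf 1. Gene models of 9311 were enriched more often than identifiers that begin with AK: 17.1% of 509 (95% exact binomial interval 13.9% to 20.7%) against 7.07% of 3958 (6.29% to 7.92%), among features that reached 10 CPM in any tissue. Among features with a highest value of 10 to 30 CPM the shares were 15.9% and 5.21%. Leaf libraries used fewer features: at 118083 counts outside the abundant features, 10244 features were detected in tillering leaf and 11832 in flowering leaf, against 15011 in callus and 15159 in the library titled seedling root. Outside the abundant features, 26 features took 50% of the counts in tillering leaf and 990 in the library titled seedling root. Each tissue had 1 library, so none of these differences has a replicate check.

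The size of a difference between libraries of a single tissue gives a rough scale for the pairs that follow. At 118083 counts, 4.89% to 17.1% of the features that reached 10 counts were at least 4-fold apart between libraries of callus or of booting panicle (9 pairs), and 9.20% to 71.4% between libraries of different tissues (69 pairs), leaving out the 203 bp callus library in both. That library was 21.7% to 27.4% apart from the other callus libraries and 6.08% from filling panicle. None of the 9 pairs sets single-end libraries against each other, so preparation and read type may add to their range. These shares are of thinned counts without TMM, whereas the pairs below use CPM with TMM unless stated. Counting noise alone gave at most 8.5 features per comparison. Intervals given with counts are 95% exact Poisson intervals, those of ratios are exact binomial, and both cover counting error only.

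The library titled seedling shoot shared the transcripts of leaf. Of 505 features at least 4-fold higher in both leaf libraries than in callus, booting panicle and filling panicle, 469 were higher in the library titled seedling shoot than in the one titled seedling root and 29 lower, with median values of 11.2 and 0.717 CPM. In all, 827 features differed at least 4-fold between the pair, 575 higher in the library titled shoot and 252 in the library titled root. AK068555 had 3393 counts (3280 to 3509) in the library titled shoot and 0 in that titled root, at least 1611-fold, and AK099574 had 1491 (1416 to 1569) and 1, a ratio of 2124 (381 to 83928). In the other direction AK103618 had 813 (758 to 871) and 2 counts, a ratio of 285 (78.8 to 2361), and AK105219 had 973 (913 to 1036) and 3, a ratio of 228 (77.7 to 1106).

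Leaf at tillering and at flowering differed least with TMM: 144 features were at least 4-fold apart, 5.78% of those that reached 10 CPM, of which 102 were higher at flowering and 42 at tillering. At 118083 counts the share was 9.20% of 1641 features, the lowest of the 69 pairs of different tissues and within the range of 4.89% to 17.1% between libraries of a single tissue. ClONE_NAMEJ100088D24 was 12.3-fold (8.21 to 19.2) and AK062478 10.8-fold (6.29 to 20.1) higher at flowering, with 433 and 213 counts. AK105627 was 14.6-fold (9.60 to 23.3) and AK120334 12.1-fold (8.18 to 18.4) higher at tillering, with 249 and 248 counts. The balance of directions depended on the scaling: flowering leaf was higher in 70.8% of the differing features with TMM and in 358 of 367 with CPM taken over the library total, where flowering and filling panicle differed in fewer features, 356.

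From booting to flowering, 514 features of the panicle were higher and 232 lower by at least 4-fold. AK068555, the feature that also led in the library titled seedling shoot, went from 0 to 1276 counts (1207 to 1348), at least 552-fold, and AK121385 from 0 to 826 (771 to 884), at least 358-fold. AK060655 fell from 122 counts (101 to 146) to 1, a ratio of 93.9 (16.5 to 3740), and AK107197 from 1158 (1092 to 1227) to 27, a ratio of 33.0 (22.6 to 50.3). The share that was higher at flowering, 68.9%, was 16.1% of 1731 features with CPM taken over the library total, so the balance of directions was not settled.

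From flowering to filling, 203 features of the panicle were higher and 266 lower by at least 4-fold. The share higher at filling, 43.3%, was 50.2% with a fold of 2 and 30.6% with CPM taken over the library total, so this balance was not settled either. AK070978 went from 2 to 1061 counts (998 to 1127), a ratio of 369 (102 to 3051), and AK070921 from 0 to 340 (305 to 378), at least 78.8-fold. AK063132 went from 434 counts (394 to 477) to 0, at least 208-fold lower, and ClONE_NAMEJ053089D02 from 693 (642 to 747) to 4, a ratio of 249 (96.8 to 917).

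At flowering, leaf and panicle differed in 1028 features by at least 4-fold, 722 higher in leaf and 306 in panicle. AK121385 and AK063132 had 826 and 434 counts in the flowering panicle and 0 in the leaf, at least 245-fold and at least 129-fold higher. AK120440 had 245 counts (215 to 278) in leaf and 1 in panicle, a ratio of 276 (49.0 to 10933), and AK099736 had 136 (114 to 161) and 1, a ratio of 153 (27.0 to 6088).

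**Figure D4:**
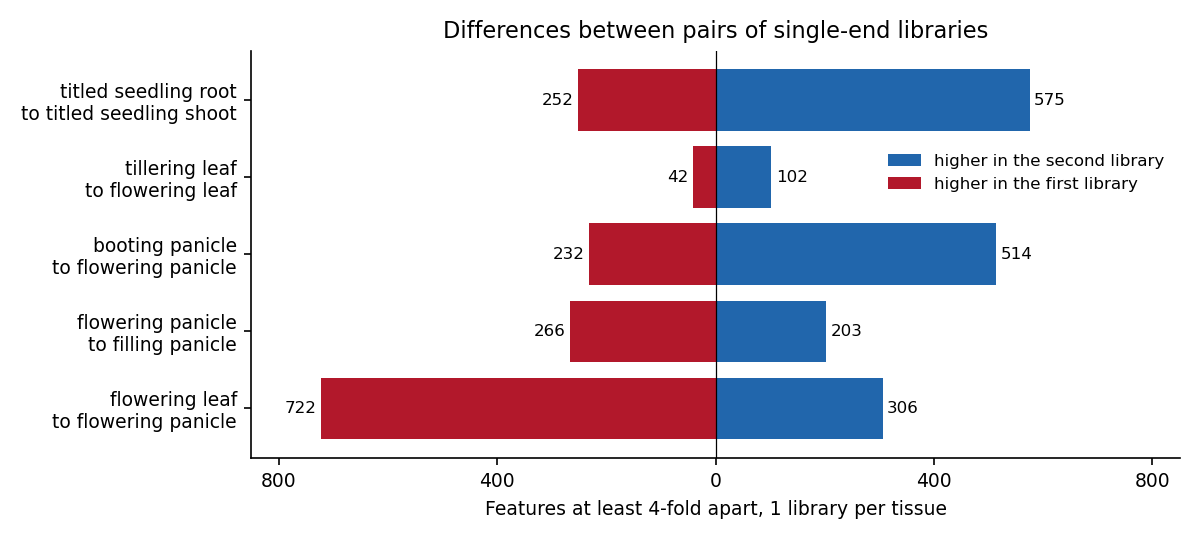
Number of features at least 4-fold apart (x axis), with at least 10 CPM in the higher library, in 5 pairs of single-end libraries (y axis; 1 library per tissue, no error). Bars to the right count features higher in the second library of the pair and bars to the left those higher in the first. Tillering and flowering leaf differ in 144 features and flowering leaf and panicle in 1028.

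Small RNAs of the pool were mainly 24 nt long. Of 4866269 reads in 2682621 distinct tags, 58.3% were of 24 nt, 15.8% of 21 nt, 12.7% of 23 nt and 4.45% of 22 nt, and the 95% exact binomial interval of the first was 58.2% to 58.3%. Among 24 nt reads 46.5% began with A, and among 21 nt reads 64.2% began with U (64.1% to 64.3%). Tags read once made up 83.0% of the distinct tags and 45.8% of the reads.

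Reads identical to 26 of 29 listed plant miRNAs were found, 7.22% of all reads (7.19% to 7.24%). The sequence of miR168, TCGCTTGGTGCAGATCGGGAC, which targets the mRNA of the Argonaute protein AGO1, had 269780 reads, 5.54% of all reads and 76.8% of the miRNA reads. miR156, a regulator of SPL transcription factors, followed with 29807 reads, then miR528 with 19487, miR167, which targets auxin response factors, with 16549, miR166, which targets class III HD-ZIP transcripts, with 7872, miR172 with 3006 and miR535 with 2463. The other 19 detected miRNAs had 2 to 508 reads. The exact listed sequences of miR395, miR398 and miR399 had 0 reads, with an upper 95% limit of 7.58e-05% of the reads each. With ends shifted by up to 2 nt, miR395 had 5 reads in 2 tags. Of the 10 most read tags, 5 were listed miRNAs. The third, TGAAGCTGCCAGCATGATCTGA, which differs from the listed miR167 sequence only at the 3' end, had 19509 reads. The sixth, TTGACAGAAGAGAGTGAGCAC, which contains the listed miR156 sequence, had 11951. Neither counts in the order and shares above, which are of exact listed sequences and not of miRNA families. The others were GGGGATGTAGCTCAGATGGT with 6286 reads, GGGGATGTAGCTCAGATGGTA with 5538 and TGGGAGTTCATGAAGCGGTCA with 5257, none of them on the list. Leaving out the listed miRNAs, 39.2% of 21 nt reads began with U. As 1 pool of 8 tissues, the library allowed no comparison between tissues.

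**Figure D5:**
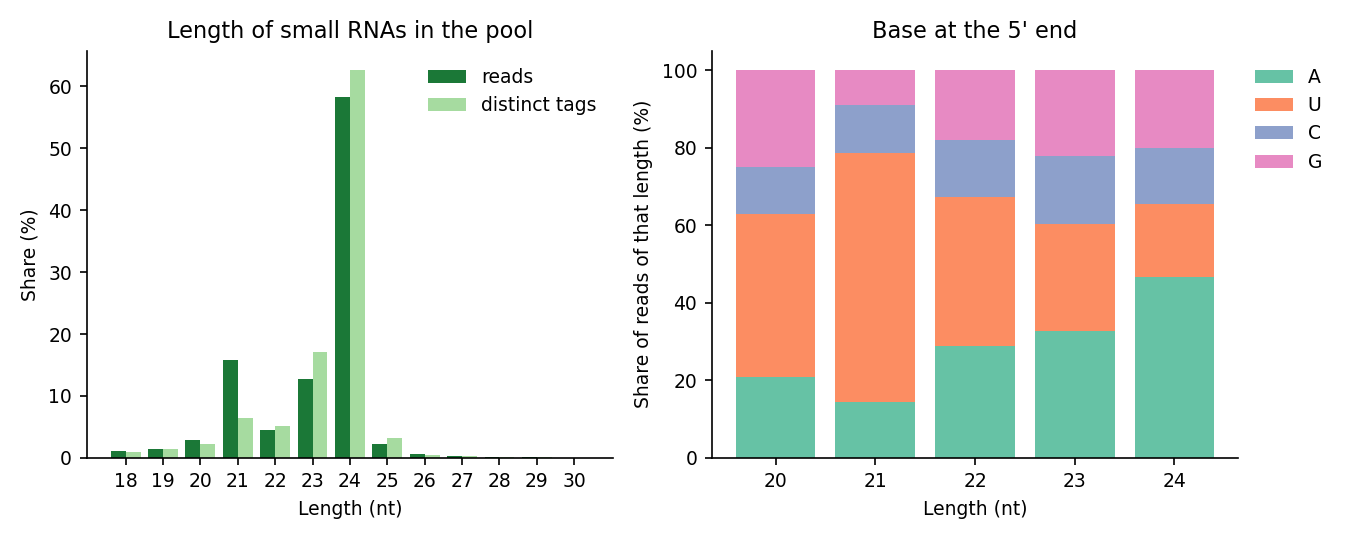
Left, share of reads and of distinct tags (y axis, %) by length (x axis, nt) in the small RNA pool. Right, share of the reads of each length from 20 to 24 nt (x axis) that begin with A, U, C or G (y axis, %; 1 pooled library, no error). Reads of 24 nt make up 58.3%, and U begins 64.2% of the 21 nt reads.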

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

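The tests on AK105158 and on the labels of the seedling libraries were chosen after the results had been seen. In groups of 4 libraries, 15 sets of values were searched for a library far from the rest, and chance marks about 1 set in 20.

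The 203 bp callus library stood apart from the other callus libraries: its mean rho with them was 0.502, against 0.643 to 0.649 for the others, and AK069616 was at 3.78 CPM there and at 0 to 0.0161 CPM in the others. The tables argue against its preparation or depth as the cause, since at equal depth the single-end callus library of the same preparation exceeded it by 0.220 in rho with the polyA callus libraries. They also argue against filling panicle RNA alone, because the 75 features enriched in callus were higher in it than in filling panicle by a median of 2.56 on the log2 scale (2.35 to 2.88). A candidate explanation that stays open is RNA of filling panicle mixed into it, which needs the 51 features enriched there to stand above the other callus libraries, and their median log2 ratio was 4.79 (4.25 to 5.61). Features enriched in the library titled seedling shoot stood in it at 23.5% of their level there by summed CPM, against 7.89% in filling panicle and 2.25% to 3.43% in the other callus libraries, but their medians of 3.42 and 2.33 CPM in it and in filling panicle were closer, so a few features may carry the sum, and a callus culture in another state was not tested.

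AK105158 took very different shares of runs of a single library: 30.6%, 3.40% and 2.64% in the 360 bp and 17.4%, 4.71% and 0.363% in the 414 bp booting panicle library, and 3.71% and 0.0688% in the 206 bp callus library. The highest share was 54.0 times the lowest in runs of a single library, and 4 of 6 libraries with several runs had a ratio above 3. These ratios restate the pattern and are no separate test of the RNA content of the library. The tables argue against a run whose whole profile differs, since the other features correlated at 0.944 or more between such runs. Runs were assigned to libraries by the insert size in the labels, and if this is right no biological explanation applies. A contaminant or a difference between sequencing batches may remain, which no label or sequence here could decide.

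For the seedling libraries, titles and tissue fields disagree. Over 505 features high in both leaf libraries, the library titled shoot exceeded the one titled root by a median log2 ratio of 2.61 (2.44 to 2.83). This argues against exchanged titles and is consistent with exchanged tissue fields, although leaf transcripts were chosen from other libraries of this series and neither library has a replicate.

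The single-end booting panicle library had 16418 features detected against 27516 to 29743 in the other 3, with 1036291 counts against at least 10042669.

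Other splits of the 8 libraries were tried for both tested comparisons. For booting panicle against callus, 1 of 35 splits, the real one, gave as many as 4147 features. The highest of the others gave 311. This was below the bound set beforehand for chance, but 1 of 35 is the lowest share possible. The other splits mixed the tissues, whose difference then counted as spread within a group, so few calls were likely in them. The splits therefore cannot exclude chance. For mixed against polyA preparation, 2 of 56 splits, the real one among them, gave as many as its 91 features. This was also below that bound, but another split gave more, so the count does not set the preparation apart from other groupings. The highest other split gave 1006, set the single-end, 206 and 180 bp callus libraries against the rest and, with tissue as a term, parted the 203 bp callus library from the other callus libraries, which points to a structure of the samples.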

How the results depend on the processing

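Alternatives without abundant features, without features listed at 0, with CPM taken over the library total, and those of the preparation with DESeq2, upper quartile scaling or no tissue term were chosen after seeing the data. Where a value moved, the cause was not tested unless the rule itself gives it, as a stricter fold or minimum does. The gene list alternatives and those for normalized values were not run, as no identifier matched and the files hold counts.

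For booting panicle against callus, every alternative called features in both directions. The count was 14263 with runs as samples, of which 51.0% were higher in booting panicle against 35.5%, 16945 with 75 bp runs only, and 2664 with a minimum mean of 5 CPM. Runs of a library repeat it, so runs as samples overstate the number of replicates. The 75 bp runs came from a single library of each tissue, so that setting leaves out the spread between libraries. Leaving out each library gave 2058 (without the 180 bp callus library) to 5313 (without the 203 bp callus library), with 2334 without the 206 bp callus library. The replicate numbers do not pair the runs: deviations of same-numbered runs correlated above 0.1 in 10 of 14 pairs (-0.200 to 0.264) and 2 runs correlated best with their own number. The replicate block, with runs as samples, gave 15509 features.

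For mixed against polyA preparation the count of 91 became 1173 without a filter, 43 with a minimum mean of 5 CPM, 785 with DESeq2 and 3 without a tissue term, and 0 to 117 when each library was left out (0 without the single-end booting panicle library, 4 without the 178 bp booting panicle or the 180 bp callus library and 30 without the 206 bp callus library).

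The 439 enriched features became 1275 and 188 with folds of 2 and 8, 259 with a minimum of 20, 208 with a pseudocount of 5 and 663 with CPM taken over the library total. With a fold of 2, then 8, then a minimum of 20, then a pseudocount of 5, the counts were 1526, 516, 385 and 376 between the seedling libraries, 699, 19, 79 and 45 between leaves, 1342, 419, 368 and 342 from booting to flowering panicle, 1091, 233, 242 and 191 from flowering to filling, and 1895, 456, 634 and 473 between flowering leaf and panicle. With a minimum of 5 they were 1531, 283, 1247 and 808 in the first 4. CPM taken over the library total gave 367 between leaves and 1731 from booting to flowering; that scaling shifted all features by 0.79 and -1.43 on the log2 scale in these pairs, and median-ratio scaling by -0.15 and -0.23. The balance turned from booting to flowering with it (16.1% higher at flowering against 68.9%), between leaves with a fold of 8 (47.4% higher at flowering) and from flowering to filling with a fold of 2 (50.2% higher at filling). With CPM over the library total the share higher in the library titled shoot than in that titled root also moved, from 69.5% to 59.3%. The share higher at filling than at flowering moved from 43.3% to 30.6%, and that higher in flowering panicle than in flowering leaf from 29.8% to 15.0%.

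Counting distinct tags, then tags read at least 2 times, the share of 24 nt was 62.6% and 56.5%, that of 21 nt 6.43% and 23.6%, that of A in 24 nt 44.2% and 49.5%, and that of U in 21 nt 33.3% and 71.4%. Allowing ends shifted by up to 2 nt, 7.69% matched a listed miRNA. Limiting tags to 18 to 30 nt changed nothing, as all tags have these lengths. Depth limits the single-end libraries, where 118436 to 335930 counts lay outside the abundant features.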

Other observations

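The tests on offsets of equal paired length, for 21 and 24 nt tags, were chosen after the results had been seen, and so was the set of leaf features over panicle stages.

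Features high in leaf and low in callus differed between the single-end panicle libraries. The 674 features with at least 10 CPM in both leaf libraries and at least 4 times their callus value had median values of 0.886, 6.33 and 2.00 CPM in the booting, flowering and filling panicle. Their median log2 ratio was 1.82 from booting to flowering, with 620 higher and 43 lower, against 0.36 to 0.59 over 95% of 10000 random lists matched on mean CPM. From flowering to filling it was -1.21, with 100 higher and 566 lower, against -0.20 to -0.03. With CPM taken over the library total the ratios were 1.01 and -1.26, in the same directions. From booting to filling the median was 0.60 with TMM (random lists 0.31 to 0.49) and 0 over the library total (upper end of the random lists -0.80), so the set lay above its random lists with both while its own ratio moved with the scaling. The random lists were not matched on being low in callus. Single-end callus correlated more with booting (0.570) and filling (0.508) than with flowering panicle (0.466). Picking features low in callus may therefore itself lower the set at booting and filling, which these lists cannot exclude. Each stage had 1 library, so a course over development is not shown.

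Complementary tags of 21 nt were most frequent as duplexes with a 3' overhang of 2 nt. Of 172373 distinct 21 nt tags, 6962 had an exactly complementary partner at that offset, 2.32 times the median of the other offsets from -6 to 8 and above the highest of them, 4951. Set against the mirrored 5' overhang of the same paired length, the ratio was 3.07 at 2 nt and 0.981 to 1.25 at 1, 3, 4, 5 and 6 nt. Both are consistent with Dicer-like cleavage of double-stranded RNA, as a hypothesis. For 24 nt tags the number at 2 nt, 57018, was 1.01 times the median of the other offsets, which met the bound set beforehand for counting against such cleavage. After this was seen the bound was judged wrong, because partners became more frequent as the paired part shortened, from 39816 at 0 to 97194 at 8 nt and 69019 at -6 nt, so other offsets are no fair level and the planned test leaves the 24 nt tags undecided. At equal paired length the ratio was 1.24 at 2 nt against 0.894 to 1.03 at the others, a smaller excess in the same direction, from a test and bound chosen after the first had failed.

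Most reads of the more abundant listed miRNAs kept the listed 5' end. Over 12 listed miRNAs with at least 100 reads, counting tags whose ends were shifted by up to 2 nt, a median of 94.4% of reads kept the listed 5' end. miR397 had 49.9%, miR156 69.6% and miR166 81.2%. The shares with the whole listed sequence were 49.2%, 69.1% and 74.3% in these. Few reads that kept the 5' end thus differed at the 3' end, and the 5' side was not the more uniform one. For miR319 and miR820, which had fewer exact reads, 6.56% and 4.74% of the reads of such tags had the listed sequence. The listed 5' end was kept by 92.3% and 96.8% of them.

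AK103558, high in callus, had 16 counts in the library titled seedling root and 0 in the single-end libraries of the other 5 tissues apart from callus and booting panicle. In none of the 8 single-end libraries were 7313 features (20.8%) seen, which were 37.6% of the gene models named by chromosome of 9311 and 9.74% of the identifiers that begin with AK.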
